A study of Homo sapiens with 8 samples.

How the data were processed

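Expression was measured on 8 one-colour Affymetrix arrays hybridised with biotin-labelled cRNA from BE(2)-C neuroblastoma cells, per the labels' protocols. The groups were SCRAMBLE shRNA with DMSO, SCRAMBLE shRNA with doxycycline, DOT1L shRNA with DMSO and DOT1L shRNA with doxycycline, 2 arrays each, sampled after 96 h. The values used are the deposited log2 expression values of the series table. They were made with Affymetrix Expression Console, per the submitters' processing notes; its version, the summarisation method and the normalization method are not given in the sources used here. The log base was inferred from the values, which run from 0.65 to 13.7 with no negative or missing ones, as log2 of scanner intensities does. Array medians between 4.31 and 4.38 and quartiles that nearly coincide show that the deposited log2 values had been normalized across arrays. Scanner files were not used here, so the background correction of the authors was kept as it is.

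Probe sets were named from the platform's annotation, with symbols updated through the gene identifier, and all 16098 named probe sets matched the reference gene table of assembly GRCh38.p14. Of 53617 probe sets, 16098 were paired with exactly 1 symbol and are called named. The other 37519 are called unnamed here. Probe sets paired with several symbols, if any, were not counted apart and would be among the unnamed. The genome build of the array design is not stated in the sources used, and no coordinates are given. The named probe sets held 14884 symbols, 779 of them with several probe sets, of which the one with the highest mean over the 8 arrays was taken. Genes with a mean over the 8 arrays below the 25th percentile (log2 4.06) were left out, and 11163 genes were tested. DOT1L and MYCN have no probe set paired with their symbol alone, and MYC fell below the filter.

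The test for genes was limma (version 3.58.1 in R 4.3.3), with lmFit, contrasts.fit and eBayes on 4 group means over the 8 arrays, so that all groups share 1 estimate of the spread (4 residual and 5.06 prior degrees of freedom). The contrasts were DOT1L doxycycline minus DOT1L DMSO, SCRAMBLE doxycycline minus SCRAMBLE DMSO, the difference of these 2 responses, and DOT1L minus SCRAMBLE under DMSO and under doxycycline. A gene passed with a Benjamini-Hochberg adjusted p under 0.05 over the 11163 genes, two-sided. The labels do not say whether the 2 arrays of a group come from separate cultures, so the p-values measure the spread between these samples only. The labels number the arrays of each group 1 and 2 without saying what a number marks. Same-numbered arrays deviated together from their group means in all 6 pairs of groups (r across genes 0.120 to 0.363), and the second principal component (23.4% of the variance) separated the numbers. Without a block this shared deviation stays in the error of the fit, so counts at an unadjusted p can fall below the number expected by chance. Where the replicate number as a block moved a count of calls, that count is given beside the result.

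The groups, tests, gene lists and the rule for named genes were fixed before the data were examined. For the DOT1L response and for the difference of responses the rule took the 12 genes with the largest rise and the 12 with the largest fall among those that passed, and for the other 3 contrasts the 5 largest in each direction. Where fewer passed, the smallest p in that direction filled the places. DOT1L, MYCN, MYC, ODC1 and E2F2 were to be reported whatever their values, and from each gene list up to 4 members with the smallest p. Of the genes that the rule picked between the lines under doxycycline, 1 is not reported here. The 28 gene lists were written from general knowledge of the pathways, and 26 had at least 5 tested members. They were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast, and again with an estimated correlation and with fry, whose directional p asks whether a list moves one way and whose mixed p asks whether its genes change in either direction. Marker lists of 7 other cell types were adjusted among themselves. Counts within a list cover its tested members only, which for the respiratory chain and the matrix and integrin lists are a minority of the genes written.

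The code was tested on simulated data, 20 simulations with 200 changed genes of 11163 each. The simulations used the real genes' means and their spreads after moderation by eBayes, not the observed spreads. Genes were simulated as independent and without a shared replicate deviation, so the shares below test the code and are not the power on the real arrays. For the DOT1L response it called 23.3% of changes of 0.5 log2, 95.0% of changes of 1 log2 and 99.8% of changes of 1.5 log2, with 5.55% false among the calls. For the difference of responses it called 3.60%, 66.1% and 97.5%, with 5.99% false. A shift of 0.1 log2 in the mitochondrial ribosome list, simulated with independent genes, was called in 19 of 20 simulations.

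Alternatives were the replicate number as a block, quantile normalization of the deposited values again, median centring of each array, no filter and a filter at the 50th percentile, the mean of a symbol's probe sets, every probe set of the table, eBayes with trend and robust, arrayWeights, the 4 arrays of a comparison alone, a fold of at least 1.5 or an adjusted p under 0.1 as the threshold, each array left out in turn, and lists without ODC1 and E2F2. Added after seeing the data were the list tests between the lines, a contrast of the DOT1L doxycycline arrays with the mean of the other 3 groups, a fit of the unnamed probe sets, and the replicate number as a block in both of these fits. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.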

Results

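BE(2)-C is a human neuroblastoma cell line, described in the labels as MYCN-amplified. The cells carried a hairpin RNA that doxycycline switches on, either one against DOT1L, an enzyme that methylates histone H3, or a SCRAMBLE control hairpin. Each line was kept for 96 h with the DMSO vehicle or with doxycycline, which gave 4 groups of 2 arrays and 8 one-colour Affymetrix arrays in all. The deposited log2 values covered 53617 probe sets per array, with array medians between 4.31 and 4.38. Of the probe sets, 16098 were paired with exactly 1 gene symbol, and the other 37519 are called unnamed here. The tests covered 11163 genes. Pearson's r between the 2 arrays of a group, across genes, was 0.985 in SCRAMBLE cells with DMSO and 0.989 to 0.990 in the other 3 groups. The number of arrays limits the precision, and the 95% interval of a typical difference between 2 and 2 arrays reached 0.33 log2 to either side. Differences are given in log2 with their standard error (SE), n = 2 arrays per group.

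DOT1L, the target of the hairpin, has no named probe set here, meaning one paired with its symbol alone, and neither has MYCN. Whether either gene shares a probe set with another symbol was not checked. The knockdown therefore could not be checked on the named probe sets, and the groups below are named as the labels give them. MYC, which belongs to the same gene family as MYCN, had 1 probe set, with log2 values of 3.34 to 3.64 on the 8 arrays. All of these lie below the level of 4.06 required for testing.

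The first comparison asks which transcripts change when the DOT1L hairpin is induced. CD9, a tetraspanin of the cell surface, fell from 5.92 ± 0.22 (SD, n = 2) with DMSO to 4.26 ± 0.08 (SD, n = 2) with doxycycline, a 3.16-fold decrease. Its log2 change was -1.66 ± 0.16 (SE; 95% interval -2.02 to -1.30; limma adjusted p = 0.0281). In SCRAMBLE cells CD9 stood at 6.20 ± 0.26 (SD, n = 2) with DMSO and 6.19 ± 0.07 (SD, n = 2) with doxycycline. The level with doxycycline is close to the 4.06 required for testing. CD9 was the single gene of 11163 that passed, and 0 genes passed in the higher direction. At an unadjusted p under 0.05 there were 721 genes, 505 lower and 216 higher, where 558 would be expected by chance.

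The other genes that the naming rule picked for this comparison did not pass, and their values follow. JUP, which encodes plakoglobin of desmosomes and adherens junctions, had a log2 difference of -0.91 ± 0.11 (adjusted p = 0.0565 by limma with Benjamini-Hochberg adjustment). IGFBP7, a secreted protein that binds insulin-like growth factors, had -1.13 ± 0.17, and GPR155 -0.86 ± 0.11. VDAC1, the main channel of the outer mitochondrial membrane, had -0.94 ± 0.12, and CILK1, a kinase of the primary cilium, -1.24 ± 0.14. LGMN, the lysosomal protease legumain, had -0.87 ± 0.11, and LDB3 -1.40 ± 0.19. TMEM109 had -1.12 ± 0.17 on its brighter probe set and 0.36 on a dimmer one. TMEM267 had -0.78, COPS8, a subunit of the COP9 signalosome, -0.80, and ADCYAP1, which encodes the neuropeptide PACAP, -0.73. On the higher side CBLN2, a secreted synapse organiser, had 0.72 ± 0.11 and LHCGR, the receptor for luteinising hormone, 0.65 ± 0.12. KDM6B, a histone H3 demethylase, had 0.59 ± 0.12, DPYSL3, a cytoskeletal protein of growing axons, 0.61 ± 0.13, and NPTX1, a neuronal pentraxin, 0.49 ± 0.11. CSH1 had 0.82, FBXW10B 0.75, SAE1P1 0.68, MTMR11 0.65, FLJ13224 0.54, NGEF 0.50 and LRRC10 0.47. CD9 passed on leaving out either SCRAMBLE DMSO array (limma adjusted p = 0.0465) and missed the threshold on leaving out either SCRAMBLE doxycycline array (0.0967), DOT1L DMSO replicate 1 (0.274) or 2 (0.122), or DOT1L doxycycline replicate 1 (0.188) or 2 (0.176). With the replicate number as a block 12 genes passed, all lower, among them CD9, CILK1, GPR155, IGFBP7, JUP, LDB3, LGMN and VDAC1, and without the filter on dim probe sets 0 genes passed.

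**Figure D1:**
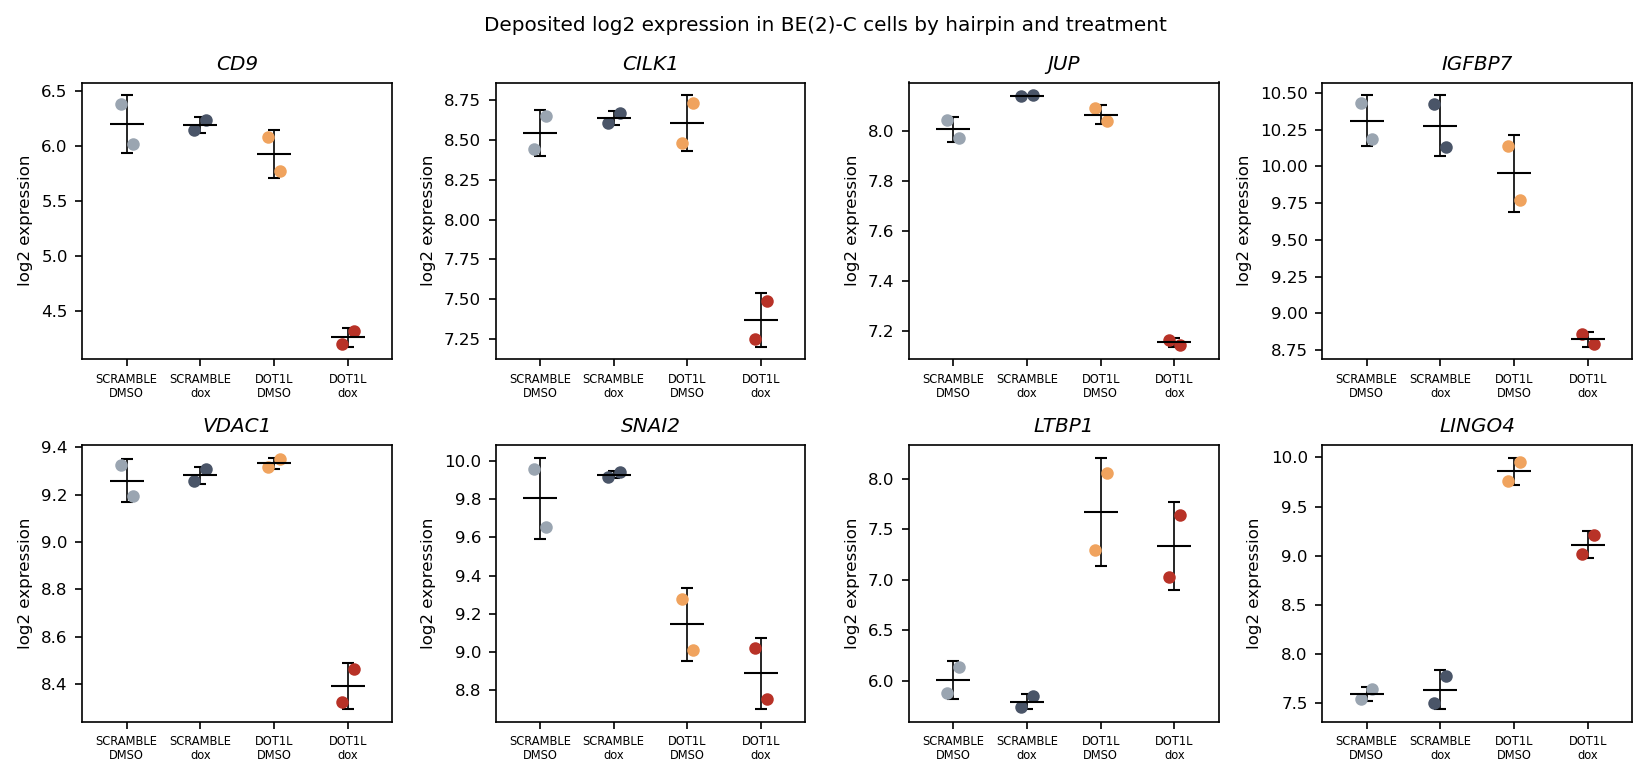
Deposited log2 expression (y axis) of 8 genes in the 4 groups of BE(2)-C cells (x axis; dox, doxycycline). Points are single arrays, and the horizontal line and bars give the mean and SD of 2 arrays. CD9 averages 4.26 in DOT1L shRNA cells with doxycycline and 5.92 to 6.20 in the other groups, while LINGO4 averages 7.60 and 7.64 in SCRAMBLE cells and 9.86 and 9.11 in DOT1L shRNA cells.

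ODC1, the enzyme that starts polyamine synthesis, and E2F2, a transcription factor of the G1/S transition, were singled out in the published study of this model. In the DOT1L shRNA cells ODC1 averaged 11.12 ± 0.08 (SD, n = 2) with DMSO and 10.83 ± 0.07 (SD, n = 2) with doxycycline, a log2 difference of -0.29 ± 0.15 (SE; 95% interval -0.64 to 0.05; limma adjusted p = 0.84). E2F2 averaged 7.55 ± 0.21 and 7.39 ± 0.05, a difference of -0.16 ± 0.13 (limma adjusted p = 0.944). Neither passed. Against SCRAMBLE cells under doxycycline ODC1 differed by -0.32 (limma adjusted p = 0.512) and E2F2 by -0.03, which became 0.0020 when each array was set to the same median and 0.0040 without DOT1L doxycycline replicate 1.

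Gene lists fixed in advance were tested with camera against all other genes, and 0 of 26 passed for induction of the DOT1L hairpin, 0 with an estimated correlation and 0 by fry. At an unadjusted p under 0.05, 3 of these lists are found by camera. They are the catecholamine and secretory granule genes, the cholesterol synthesis genes, and the immediate early and AP-1 genes. Of 13 catecholamine and granule genes 9 had negative values, among them CHGA (chromogranin A) with -0.48 ± 0.13, TH (tyrosine hydroxylase) with -0.39 ± 0.16 and CHGB with -0.33, while PCSK1N had 0.30 (camera adjusted p = 0.281 for the list, 0.949 with an estimated correlation). Of 17 cholesterol synthesis genes 14 had negative values, with MSMO1 at -0.56, STARD4 at -0.41, IDI1 at -0.38 and HSD17B7 at -0.35 (adjusted p = 0.281; 0.949 with an estimated correlation). The mean of this list was -0.36 without DOT1L DMSO replicate 2 and turned to 0.055 without DOT1L DMSO replicate 1. Of 18 immediate early genes 11 had positive values, led by DUSP6, a phosphatase that switches off ERK, at 0.97 ± 0.27 (list adjusted p = 0.401). Of 19 MYC and MYCN activated genes 12 had negative values, including RRS1 at -0.24 and ODC1 at -0.29 (adjusted p = 0.485), and since the study singled out ODC1 and E2F2, this list is not independent evidence. The same holds for the G1/S genes, with 19 of 28 negative (adjusted p = 0.545; CCNE2 at -0.36), and for the polyamine genes, with 8 of 14 negative (adjusted p = 0.885). G2/M genes were split, 13 of 28 negative with a median of 0.00 and a mean of -0.04 (adjusted p = 0.761), with CENPA at -0.47 and AURKA at -0.33.

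Among the transcription factor lists, 12 of 18 adrenergic core factors, which hold the noradrenergic identity of neuroblastoma cells, had positive values (adjusted p = 0.481), with TFAP2B at 0.53 ± 0.15 and ISL1 at 0.30. Of 17 mesenchymal state genes 11 had negative values (adjusted p = 0.602), with VIM at -0.26 and SNAI2 at -0.26. HOX genes and cofactors were positive in 14 of 25 (adjusted p = 0.485; HOXB4 at 0.42, HOXD9 at -0.35), and neuronal differentiation genes in 11 of 18 (adjusted p = 0.545; DCX at 0.42, CNTN1 at -0.49). Of 8 tested partners of DOT1L and the super elongation complex, 5 were positive (adjusted p = 0.943), with a median of 0.04 and a mean of -0.01. Polycomb genes were positive in 9 of 16 (adjusted p = 0.885; median 0.04, mean -0.01), with SUZ12 at -0.61 ± 0.16. Ribosome biogenesis genes were negative in 19 of 27 (adjusted p = 0.485). In 2 lists 1 gene passed when adjusted over the list alone, where 0 passed over all genes. These were LTV1, a factor for the small ribosomal subunit, at -0.74 (limma p of 0.0124 adjusted over the list alone and 0.177 over all genes) and PSPH, an enzyme of serine synthesis, at -0.59 (0.0457 and 0.293).

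The remaining lists did not pass either. Negative values were found in 12 of 22 ATF4 target genes (adjusted p = 0.663), 9 of 11 endoplasmic reticulum chaperones (0.485), 7 of 9 glycolysis genes (0.485), 10 of 16 hypoxia genes (0.485), 45 of 77 mitochondrial ribosome genes (0.761), 8 of 14 apoptosis regulators (0.894), 4 of 7 NF-kB genes (0.922) and 7 of 14 p53 targets (0.922; median 0.01, mean -0.04). Positive values were found in 8 of 10 interferon genes (adjusted p = 0.481), 10 of 15 nuclear encoded respiratory chain genes (0.663), 4 of 5 metallothioneins (0.761) and 4 of 6 matrix and integrin genes (0.885). The CDK inhibitors had 2 tested members and the mitochondrially encoded genes 0, so neither list was tested.

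SCRAMBLE cells served as the control for doxycycline itself and for making a hairpin. No single gene passed there, 0 of 11163 by limma, with 304 genes at an unadjusted p under 0.05 against 558 expected by chance. Genes are not independent and same-numbered arrays deviated together, so 558 is not a firm yardstick here or for the other contrasts. The genes that the naming rule picked had log2 differences between -0.74 and 0.61, each with an adjusted p of 0.999. PET100, an assembly factor for cytochrome c oxidase, had 0.58, GPR83 0.58, LILRP2 0.56, WDR11-DT 0.47 and ZNF530 0.61. COX6A2 had -0.74, EFL1P1 -0.74, VSTM5 -0.55, SMTNL1 -0.54 and TTC34 -0.47. Genes of 3 lists were slightly higher with doxycycline as groups by camera. These were nuclear encoded respiratory chain genes (13 of 15 higher, adjusted p = 0.0116; UQCRB at 0.52 ± 0.15, COX8A at 0.45, COX7B at 0.29, COX5B at 0.20), mitochondrial ribosome genes (61 of 77 higher, 0.0116; MRPS17 at 0.41, MRPS10 at 0.27, MRPL11 at 0.26) and ATF4 target genes of the integrated stress response (18 of 22 higher, 0.0404; DDIT4 at 0.33, ATF3 at 0.30, DDIT3 at 0.29, SHMT2 at 0.21). The call is lost for all 3, with adjusted p = 0.932 with an estimated correlation and 0.812 by fry, for the mitochondrial ribosome and ATF4 genes with quantile normalization again, and also on leaving out SCRAMBLE DMSO replicate 2 or SCRAMBLE doxycycline replicate 1, where 0 lists passed. Without SCRAMBLE DMSO replicate 2 COX7B turned to -0.0021 and DDIT4 to -0.054, and COX8A was 0.18 and DDIT3 0.082. ATF3 went the other way, with 0.53 without replicate 2 and 0.074 without replicate 1. Markers of epithelial cells were lower in the same comparison in 5 of 6 genes (camera adjusted p = 0.0211; 0.118 with an estimated correlation). This call uses the same SCRAMBLE DMSO arrays, and the marker lists were not tested without single arrays.

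Whether the response to doxycycline differed between the lines was tested directly as the difference of the 2 responses. No gene passed this test, 0 of 11163 by limma, with 576 genes at an unadjusted p under 0.05 against 558 expected by chance and a smallest adjusted p of 0.385. With the replicate number as a block 1 gene passed, CYSLTR2, at -1.96 ± 0.45 without the block, which the naming rule did not pick. CD9 had the smallest p, with a difference of -1.65 ± 0.23 (95% interval -2.16 to -1.14; limma adjusted p = 0.385). The other lower genes picked by the naming rule were JUP at -1.05 ± 0.16, CILK1 at -1.33 ± 0.20, VDAC1 at -0.96 ± 0.17, TMEM109 at -1.41 (-0.49 with the mean of its probe sets), TRIM16 at -0.98, COPS8 at -0.91, MC4R, the melanocortin receptor, at -0.90, LGMN at -0.89, TMEM267 at -0.80, ADCYAP1 at -0.80 and GPR155 at -0.76. The higher genes were FBXW10B at 1.01, HOXD12 at 0.89, DSCAML1 at 0.87, LHCGR at 0.86, FLJ13224 at 0.82, NPTX1 at 0.79, CEACAM3 at 0.79, CBLN2 at 0.72, FOXD4L1 at 0.71, NGEF at 0.69, AHR, the aryl hydrocarbon receptor, at 0.65 and NPAS1 at 0.61. ODC1 differed by -0.27 and E2F2 by -0.24 ± 0.19 (limma adjusted p = 0.966 for both). Of the 26 lists 0 passed by camera, 0 with an estimated correlation and 0 by fry. Camera gave the smallest adjusted p, 0.119, to 4 lists, namely catecholamine and granule genes (12 of 13 negative; CHGA at -0.59), cholesterol synthesis genes (16 of 17 negative), ATF4 targets (18 of 22 negative) and mitochondrial ribosome genes (60 of 77 negative), each with an adjusted p of 0.925 with an estimated correlation. The means of these 4 lists, in the same order, were -0.098, -0.012, -0.075 and -0.058 without SCRAMBLE DMSO replicate 2, where they did not pass, and -0.37, -0.43, -0.27 and -0.15 without SCRAMBLE DMSO replicate 1, where they passed. On simulated data with 200 changed genes of 11163, this test called 66.1% of changes of 1 log2 and 97.5% of changes of 1.5 log2. Those genes were simulated as independent and without a shared replicate deviation. The shares do not carry over to the arrays, where CYSLTR2 at -1.96 and CD9 at -1.65 did not pass without the block. Across the 11163 genes the 2 responses had a Pearson's r of -0.04 and a Spearman's rho of -0.05, with no shared arrays, and genes are not independent replicates.

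Without doxycycline, the lines differed in 1 gene that passed. LINGO4, a membrane protein with leucine-rich repeats and an immunoglobulin domain, stood at 9.86 ± 0.14 (SD, n = 2) in DOT1L shRNA cells and 7.60 ± 0.07 (SD, n = 2) in SCRAMBLE cells, 4.79-fold higher (log2 2.26 ± 0.14; limma adjusted p = 0.000775). At an unadjusted p under 0.05 there were 902 genes, 512 higher and 390 lower in DOT1L shRNA cells. With the replicate number as a block 10 genes passed, 6 higher and 4 lower, among them LINGO4, LTBP1, LCP1, ENPP1 and CD200. Without the block the other genes picked by the naming rule did not pass, with adjusted p between 0.274 and 0.294. LTBP1, which holds latent TGF-beta in the matrix, had 1.67 ± 0.26, FGF13 0.92, CFAP300 0.86 and GALM 0.72. LCP1, the actin bundling protein L-plastin, had -1.72 ± 0.31, ENPP1 -1.17, FBXW10B -1.13, CD200 -1.10 and ADCYAP1R1, the receptor for PACAP, -1.03. The list tests under DMSO and between the lines under doxycycline were added after seeing the data. By camera 3 lists were higher as groups in DOT1L shRNA cells. These were nuclear encoded respiratory chain genes (14 of 15, adjusted p = 0.00518; UQCRB and COX7B both at 0.55), ATF4 targets (21 of 22, 0.00518; DDIT4 at 0.60, SHMT2 at 0.33, MARS1 at 0.31) and mitochondrial ribosome genes (63 of 77, 0.0294; MRPL16 at 0.42, MRPL11 at 0.33). They are compared with the same SCRAMBLE DMSO arrays as above, and the call is lost for all 3 with adjusted p = 0.940 with an estimated correlation, 0.352 by fry, for the mitochondrial ribosome genes with quantile normalization again and median centring, and for all 3 on leaving out SCRAMBLE DMSO replicate 2 or DOT1L DMSO replicate 1, where 0 lists passed. Without SCRAMBLE DMSO replicate 2 COX7B was 0.25 and DDIT4 0.21. Epithelial markers were lower in 4 of 6 genes here (camera adjusted p = 0.0361; 0.145 with an estimated correlation; 0.0441 by fry). This call too uses the SCRAMBLE DMSO arrays and was not tested without single arrays. SNAI2 at -0.66, HEY1 at 0.64, GCH1 at 0.79 and STC1 at 1.24 passed when adjusted over the list alone and not over all genes.

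With doxycycline in both lines, 51 genes differed, 43 lower and 8 higher in DOT1L shRNA cells. CD9 was 3.80-fold lower (log2 -1.93 ± 0.16, limma adjusted p = 0.00796), and LCP1, at 4.43-fold lower, had the largest decrease (-2.15 ± 0.31, limma adjusted p = 0.0381). Also lower were CYSLTR2, a receptor for cysteinyl leukotrienes, at -2.03 ± 0.32, and ADCYAP1R1 at -1.60 ± 0.16. Of the higher genes, LTBP1 was 2.92-fold higher (1.54 ± 0.26, limma adjusted p = 0.0498) and LINGO4 2.78-fold higher (1.47 ± 0.14, limma adjusted p = 0.0118). PCDHB12, a protocadherin, at 1.25 ± 0.21, NCAM2, a neural cell adhesion molecule, at 1.08 ± 0.15, and EPHA6, an ephrin receptor, at 0.97 ± 0.16 followed.

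The following genes among the 51 were chosen after their values were seen. CNTFR and LIFR, which form the receptor for ciliary neurotrophic factor together with gp130, had -1.28 ± 0.14 and -1.42 ± 0.24. NPY2R, a neuropeptide Y receptor, had -1.44 ± 0.19. IGFBP7 and IGFBP5, binding proteins of insulin-like growth factors, had -1.45 ± 0.17 and -1.07 ± 0.14, and SFRP1, a secreted Wnt antagonist, -1.02 ± 0.15. ASS1, an enzyme of arginine synthesis, had -1.14 ± 0.17, and ENPP1 -1.42 ± 0.21. JUP at -0.99 ± 0.11, CILK1 at -1.27 ± 0.14 and VDAC1 at -0.89 ± 0.12 also passed. On the higher side DPYSL3 had 0.90 ± 0.13, CBLN2 0.70 ± 0.11 and SERTAD4 0.74 ± 0.12. These adjusted p-values, by limma with Benjamini-Hochberg adjustment, lay between 0.0145 and 0.0479. Of the genes named for this comparison, LTBP1, PCDHB12, EPHA6, LIFR, CBLN2, SERTAD4 and LTV1 did not pass with quantile normalization again, CYSLTR2, EPHA6, LIFR, SNAI2 and LTV1 did not pass with median centring, and CBLN2 did not pass with trend and robust eBayes (adjusted p between 0.0513 and 0.0697).

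Part of this difference was present without doxycycline. The 43 lower genes had a median of -1.04 between the lines with doxycycline and of -0.36 with DMSO (95% bootstrap interval over genes -0.53 to -0.27), where 37 of the 43 had the same sign. Their median response to doxycycline was -0.62 in DOT1L shRNA cells, negative in 42, and 0.05 in SCRAMBLE cells. These responses share arrays with the comparison that picked the genes, so they are not independent of it. For LCP1 the difference under DMSO was -1.72 of -2.15, for SNAI2 -0.66 of -1.04 and for CNTFR -0.59 of -1.28, whereas for JUP it was 0.06, for CILK1 0.06, for VDAC1 0.07 and for CYSLTR2 -0.07. Across the 11163 genes the line difference under DMSO and that under doxycycline had a Pearson's r of 0.375 and a Spearman's rho of 0.263, with no shared arrays. When each array was set to the same median 33 genes passed, 24 lower and 9 higher, so that the lower share was 72.7% in place of 84.3%. With the replicate number as a block 135 genes passed, 26 higher and 109 lower, among them all 51, and without the filter on dim probe sets 8 passed. Without single arrays the count lay between 0 and 22, with 0 genes without SCRAMBLE doxycycline replicate 2 or DOT1L doxycycline replicate 2, 8 without SCRAMBLE doxycycline replicate 1, 11 without DOT1L doxycycline replicate 1, 12 without either SCRAMBLE DMSO array and 22 without either DOT1L DMSO array.

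**Figure D2:**
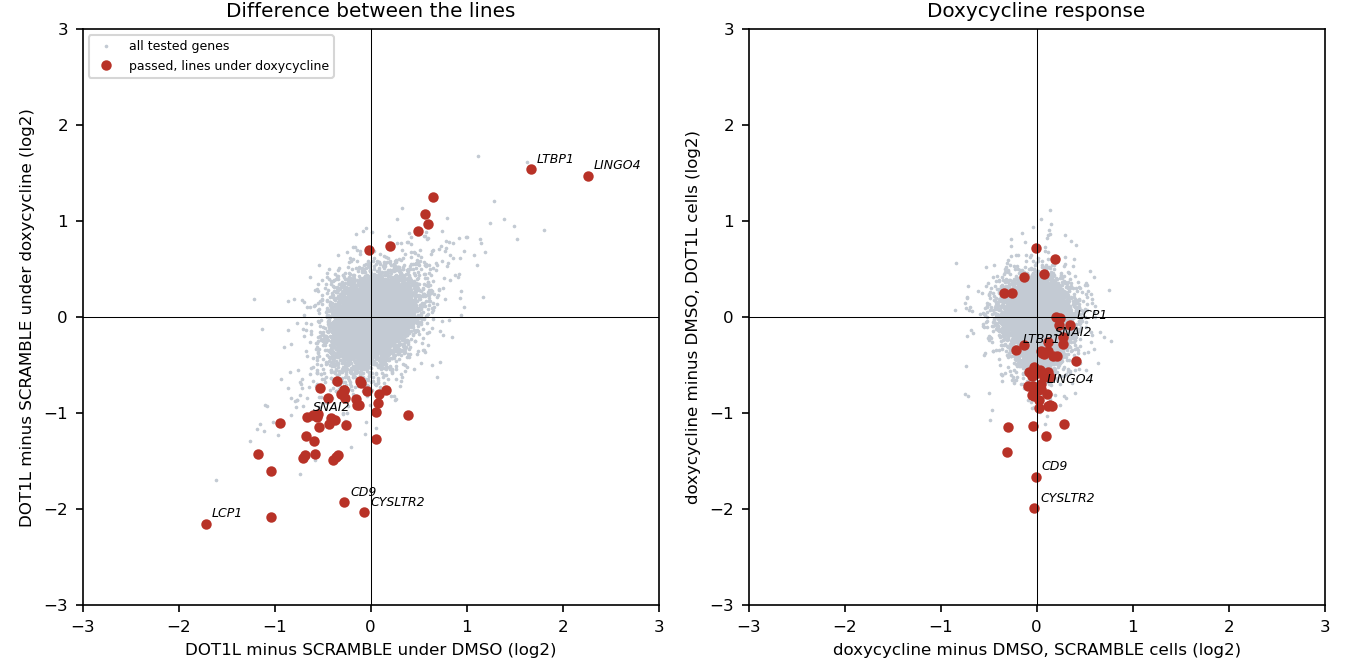
Log2 differences of the 11163 tested genes (grey) and of the 51 genes that passed between the lines under doxycycline (red). The left panel sets the difference between DOT1L shRNA and SCRAMBLE cells with DMSO (x axis, log2) against that with doxycycline (y axis, log2), and the right panel the doxycycline response of SCRAMBLE cells (x axis, log2) against that of DOT1L shRNA cells (y axis, log2). LCP1, at -1.72 and -2.15, and LTBP1, at 1.67 and 1.54, lie far from 0 under both conditions, while CD9 has responses of -0.01 in SCRAMBLE and -1.66 in DOT1L shRNA cells.

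Among the fixed lists under doxycycline, 0 of 26 passed by camera, 0 with an estimated correlation and 0 by fry, while fry's test for change in either direction, which does not compare a list with other genes, was passed by 7 lists. The adrenergic core factors were among these 7, with 10 of 18 positive (camera adjusted p = 0.315; fry in either direction 0.00772). Here 7 factors passed when adjusted over the list alone and 0 over all genes. HEY1 at 0.69 ± 0.15, ISL1 at 0.54 ± 0.12, TFAP2B at 0.57 ± 0.15, ZNF536 at 0.57, DACH1 at 0.46 and SOX11 at 0.58 had positive values, and TBX2 had -0.55 ± 0.15; ZNF536, DACH1 and SOX11 lie beyond the naming rule and were chosen after their values were seen. The mesenchymal state genes were negative in 10 of 17 (camera adjusted p = 0.609; fry in either direction 0.00772). SNAI2, the transcription factor Slug, was 2.06-fold lower and passed over all genes (-1.04 ± 0.16, limma adjusted p = 0.0418), and VIM, which encodes vimentin, at -0.49 passed only when adjusted over the list alone (0.0271). Polycomb genes were negative in 9 of 16, with SUZ12, a core subunit of PRC2, at -0.88 ± 0.16 (limma p of 0.00503 adjusted over the list alone and 0.0599 over all genes). Catecholamine and granule genes were negative in 7 of 13, with GCH1 at 0.72 and NPY at -0.57. The hypoxia list (8 of 16 negative) held STC1 at 0.98 and EGLN3 at -0.58, and the p53 targets (6 of 14 negative; median 0.08, mean -0.02) and the ribosome biogenesis genes (12 of 27 negative; median 0.02, mean -0.03) completed the 7. In the ribosome biogenesis list LTV1, at -0.85 ± 0.14, passed over all genes (limma adjusted p = 0.0479). Outside these 7 lists, DCX, the doublecortin of migrating neurons, at 0.68, DUSP6 at 1.14 and HOXD12 at 0.73 passed when adjusted over the list alone and not over all genes. Cholesterol synthesis genes, negative in 12 of 17, had the smallest camera p (adjusted p = 0.267; 0.962 with an estimated correlation).

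Markers of other cell types were checked with 7 short lists, of which those of epithelial cells (6 tested genes) and of T and NK cells (5) had enough members for a test. Induction of the DOT1L hairpin gave an adjusted p of 0.493 for both lists, and the line difference under doxycycline gave 0.9998 for both. For the difference of the responses, which also uses the SCRAMBLE DMSO arrays, epithelial markers were positive in 6 of 6 genes (camera adjusted p = 0.0577). This too was not tested without single arrays. T and NK cell markers had an adjusted p of 0.51 in SCRAMBLE cells, 0.908 for the difference of the responses and 0.566 between the lines under DMSO. Fibroblast (2 genes), Schwann cell (4), B cell (2), myeloid (3) and endothelial (3) markers had too few tested members.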

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

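All alternatives here were planned before the data were examined except the list tests between the lines, which were added after seeing the data, as were the blocked fits of the unnamed probe sets (0 passed, as without the block) and of the DOT1L doxycycline arrays against the other groups (183 genes, where 63 passed without it; the cause was not tested). The signal over background of dim probe sets and 2 arrays per group limit these results. The genes followed here include all 51 that passed between the lines under doxycycline, also those not named above. Their values under 6 alternatives (the replicate block, quantile normalization again, median centring, the mean of a symbol's probe sets, trend and robust eBayes, and arrayWeights) kept their direction and side of the threshold in 1012 gene-by-setting instances. They newly passed in 29, no longer passed in 44 and changed sign in 1, E2F2 between the lines under doxycycline at 0.0020 with median centring. A gene that passed in neither fit counts as kept, here and without single arrays. Only genes that had passed could be lost, so these totals make the calls look more stable than they are. Over the fits without single arrays, 1105 instances stayed, 336 no longer passed and 7 changed sign. With the replicate block, 12 genes passed for the DOT1L response, 0 for the SCRAMBLE response, 1 for the difference of responses (CYSLTR2), 10 between the lines under DMSO and 135 under doxycycline, and it moved no count of lists. Quantile normalization again gave 5 for the DOT1L response (CD9, CILK1, VDAC1, LDB3 and JUP) and 32 (3 higher, 29 lower) between the lines under doxycycline, and median centring gave 33 there; the cause was not tested. Trend and robust eBayes gave 10 for the DOT1L response, and arrayWeights 6 there and 85 between the lines under doxycycline; the cause was not tested. Testing 14884 genes with no filter gave 0 and 8 in these 2 comparisons, testing every one of 53617 probe sets gave 0 and 0, and 0 between the lines under DMSO, and the filter at the 50th percentile, with 7442 genes tested, gave 11 for the DOT1L response. With only the 4 arrays compared, fewer samples, they gave 0 and 1 (CD9), and with an adjusted p under 0.1, 12 and 103. LINGO4 under DMSO passed under every alternative except every probe set tested.

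Leaving out single arrays gave 0 to 1 genes for the DOT1L response, 0 to 0 for the SCRAMBLE response and for the difference of responses, 1 to 1 between the lines under DMSO and 0 to 22 under doxycycline, fits with fewer samples in which the lone array of a group is assumed to vary like the others. The DOT1L response lost CD9 without any DOT1L array or either SCRAMBLE doxycycline array. Lists passing ranged over 0 to 1 for the DOT1L response (cholesterol synthesis, without DOT1L doxycycline replicate 1 or DOT1L DMSO replicate 2), 0 to 5 for the SCRAMBLE response, 0 to 5 for the difference of responses and 0 to 5 between the lines under DMSO. The highest count came without SCRAMBLE DMSO replicate 1 in these 3; 0 lists passed without SCRAMBLE DMSO replicate 2 or SCRAMBLE doxycycline replicate 1 for the SCRAMBLE response, and without SCRAMBLE DMSO replicate 2 or DOT1L DMSO replicate 1 under DMSO. Quantile normalization again left 1 list for the SCRAMBLE response and 2 between the lines under DMSO, where median centring also left 2, no filter gave 2 for the difference of responses, and an estimated correlation or fry left 0 for the SCRAMBLE response and 0 under DMSO; the cause was not tested. Signs turned without SCRAMBLE DMSO replicate 2 in the SCRAMBLE response for COX7B (range without single arrays -0.0021 to 0.58), DDIT4 (-0.054 to 0.71) and ODC1 (-0.19 to 0.15; also 0.12 without SCRAMBLE doxycycline replicate 1), and under DMSO for ODC1 (-0.21 to 0.13; also 0.02 without DOT1L DMSO replicate 1). They also turned without DOT1L DMSO replicate 1 for the cholesterol list in the DOT1L response (-0.36 to 0.055) and without DOT1L doxycycline replicate 1 for E2F2 under doxycycline (-0.064 to 0.0040). Pearson's r between the responses was -0.104, 0.026, 0.022 and -0.040 for the 4 replicate-wise pairings. Alternatives planned for DOT1L expression were not run, because it has no named probe set here, and the 4-array fit has no counterpart for the difference of responses.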

Other observations

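The contrast of the DOT1L doxycycline arrays with the other groups, the scaling and array-pair tests and the test of SCRAMBLE DMSO replicate 2 were chosen after the results they concern were seen; the tests on held-out replicates and on the neighbours of LINGO4 were set before theirs. Set against the mean of the other 3 groups, DOT1L shRNA cells with doxycycline differed in 63 genes, 54 lower and 9 higher, by limma with Benjamini-Hochberg adjustment. As SCRAMBLE cells are among these groups, a difference between the lines also enters this contrast. LINGO4, counted as higher at 0.75, was higher still in DOT1L shRNA cells with DMSO. Both DOT1L doxycycline arrays lay beyond all other arrays in 52 of the lower and 8 of the higher genes. With the replicate number as a block, added after seeing the data, 183 genes passed, 152 lower and 31 higher, among them all 63. Genes called in this contrast and not between the lines under doxycycline, chosen after their values were seen, include SUZ12, a core subunit of the Polycomb complex PRC2, at -0.80 ± 0.13 (limma adjusted p = 0.0402), PAM, which amidates neuropeptides in secretory granules, at -0.71 ± 0.12, and SCD5, a fatty acid desaturase, at -0.78 ± 0.12. The splicing regulators MBNL2 and MBNL3 had -0.74 ± 0.12 and -0.67 ± 0.12, and DTX1, a regulator of Notch signalling, had -0.94 ± 0.15. DCX, the doublecortin of migrating neurons, was higher at 0.65 ± 0.11 (limma adjusted p = 0.0484), as was the homeobox gene IRX3 at 0.67 ± 0.10. No list passed in this contrast, 0 of 26 by camera. The count rests on both DOT1L doxycycline arrays: it was 10 without replicate 1 and 1 without replicate 2, and between 16 and 54 without any other single array, with 16 without DOT1L DMSO replicate 1 and 16 without SCRAMBLE doxycycline replicate 2.

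Probe sets unnamed here were fitted on their own above the same level. Of 17691, 0 passed in any of the 5 contrasts by limma, with 739 at an unadjusted p under 0.05 for the DOT1L response, 523 for the SCRAMBLE response, 690 for the difference of responses, 867 between the lines under DMSO and 1113 under doxycycline. Only the count under doxycycline exceeds the share of 0.05 expected by chance. The smallest adjusted p was 0.0561, under doxycycline, and with the replicate number as a block, added after seeing the data, 0 passed as well (smallest adjusted p = 0.0918 by limma).

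The excess of lower genes in DOT1L shRNA cells under doxycycline could come from the scaling of the arrays, from a difference between the lines that doxycycline did not cause, or from the hairpin. With each array set to the same median, 72.7% of the passing genes were still lower (24 of 33, 95% Wilson interval 55.8% to 84.9%, which treats genes as independent). Quantile normalization again left 90.6% lower (29 of 32). The median line difference over all tested genes was 0.0031 before and 0.035 after median centring, beside -1.04 for the 43 lower genes. These values argue against array-wide scaling as the cause of differences of this size. A stable line difference alone would leave the DOT1L response of such genes at about 0 in a held-out replicate. The 43 lowest genes picked in replicate 1 had a median DOT1L response of -0.44 in replicate 2 (95% bootstrap interval -0.61 to -0.22, all genes -0.014). Those picked in replicate 2 had -0.46 in replicate 1 (-0.68 to -0.30, all genes 0.00045). Both intervals below 0 was the criterion set beforehand, and over genes it was met, with 37 of the 43 genes below 0 in each held-out replicate. The same genes had a line difference under DMSO of -0.40 and -0.34 in those replicates, so a line difference may make up part of the pattern. Each held-out value is 1 array minus 1 array, and its interval covers genes and not arrays. The test therefore cannot tell whether a line difference is the whole cause, and an effect of the hairpin is not thereby shown. With the 2 DOT1L doxycycline arrays set against the remaining 6, 48 genes passed. Of the 28 pairs of arrays 1, the real one, gave as many, with 6 as the highest of the others (DOT1L DMSO replicate 2 with DOT1L doxycycline replicate 2). Since the pair was picked out of 4 groups after the result was seen, these splits are too few for a share under 0.05. A repression that follows DOT1L knockdown may explain part of it, but DOT1L has no named probe set here, 1 hairpin cannot separate its off-target effects, and the test of the difference of responses was passed by 0 genes, or by 1 (CYSLTR2) with the replicate number as a block.

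By camera at its preset correlation, but in 0 lists with an estimated correlation or by fry, the respiratory chain, mitochondrial ribosome and ATF4 lists were higher than in SCRAMBLE DMSO cells both with doxycycline and in the other line, and these comparisons share the SCRAMBLE DMSO arrays. A candidate explanation is SCRAMBLE DMSO replicate 2 alone: without it 0 of the 3 lists passed in either comparison, and without replicate 1 all 3 passed in both. The respiratory chain genes averaged -0.26 on that array and -0.05 on replicate 1, relative to each gene's mean over the 8 arrays, and the ATF4 targets -0.20 and -0.01. The mean shifts of the 3 lists, in the order given, went from 0.15, 0.08 and 0.11 with all arrays to 0.05, 0.03 and 0.01 without that array in the SCRAMBLE response, and from 0.21, 0.09 and 0.18 to 0.11, 0.05 and 0.08 between the lines under DMSO, where part of the shift therefore stays. The calls were also lost without SCRAMBLE doxycycline replicate 1 in the first comparison, at shifts of 0.13, 0.09 and 0.07, and without DOT1L DMSO replicate 1 in the second, at 0.18, 0.10 and 0.19; the mitochondrial ribosome and ATF4 lists also shrank in the difference of responses without SCRAMBLE DMSO replicate 2, to -0.058 and -0.075, from -0.10 and -0.17 with all arrays.

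Genes that differ between the lines already under DMSO may reflect a hairpin that is partly active without doxycycline, or a difference between the lines unrelated to it. A leaky hairpin would make the lowest genes under DMSO fall further with doxycycline; the 43 picked in replicate 1 had a median response of -0.057 in replicate 2 (95% bootstrap interval -0.13 to 0.04), and those picked in replicate 2 had -0.10 in replicate 1 (-0.20 to -0.04), intervals that cover genes and not arrays, so the hairpin and a line difference cannot be told apart on these values. LINGO4, higher in these cells under DMSO, had a response to doxycycline of -0.75 ± 0.14 in the opposite direction, which did not pass (limma adjusted p = 0.194). A change of the chromosomal region around LINGO4 would carry its neighbours, but 0 of the 10 nearest tested genes were higher under DMSO at an unadjusted p under 0.05, with C2CD4D the highest at 0.29. Why LINGO4 differs stays open.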
